A study of Mus musculus with 12 samples.

How the data were processed

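RNA sequencing was done on eyelid tissue of male C57BL/6 mice kept under 12 h of light per day. Mice were fed either a standard diet with 10 kcal% fat (control) or a high-fat diet with 60 kcal% fat, and tissue was collected at 9h, 15h or 21h. The labels name the tissue as meibomian gland, the lipid-secreting gland of the eyelid margin, while the series text describes whole upper and lower eyelids, so muscle, skin, conjunctiva and hair follicles can be part of each sample. The labels give a diet of 3 months and the series text one of 4 months, and this difference was not resolved. The 12 libraries form 6 groups of 2, one for each diet and time. Each library carries a number in its label (for example 2 and 3 in the controls at 9h). The sources used here do not say whether a library is 1 mouse or a pool, so p-values measure the spread between these libraries.

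The deposited table holds FPKM values, that is reads per kilobase of the merged exons of a gene and per unit of sequencing depth, for 21936 genes. Per the labels' protocols, total RNA was taken with Trizol and libraries were made with an Illumina kit from NEB. The submitters' processing notes name HISAT2 2.0.5, HTSeq 0.9.1 and DESeq 1.30.0 and the mouse build mm9. The step from read counts to the FPKM values, the strand setting and the annotation release are not given in the sources used here. The gene IDs and lengths behind the values fit another build than the one named: 21894 of the 21936 IDs are in GENCODE mouse release 21 on GRCm38, and with the merged exon lengths of that release 98.1% of the nonzero values are whole numbers of reads within 0.02 reads. All coordinates given are from that GRCm38 annotation and none were converted. Of the genes in the table, 21857 are protein-coding, and the others were kept in the fit where they passed the filter. Symbols were those of the table, and 36 symbols occur more than once.

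The steps between FPKM values gave a depth of 14096362 to 17889158 reads per library. One read on 2 kb of exon was worth 0.0279 to 0.0355 FPKM. The most abundant gene took 1.58% to 2.58% of the reads of a library, and the 10 most abundant genes took 6.75% to 8.87%. Counting error is therefore small for most genes named, and it grows for those near 1 FPKM.

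The design fixed before the data were examined assumed that the table might hold counts and gave a second test for FPKM values, which was used here: limma 3.58.1 with a mean-dependent prior in R 4.3.3, on log2(FPKM + 1), for the 13228 genes above 1 FPKM in at least 2 libraries. One model held a mean for each of the 6 groups and left 6 residual degrees of freedom, so all groups shared 1 estimate of the spread. Contrasts were high-fat minus control averaged over the 3 times, the same difference at each time, an F test of the interaction of diet and time, and an F test of time within each diet. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and an adjusted p under 0.05 counts as called. A fold change on the log2(FPKM + 1) scale understates the change of genes with low values. For 33 gene lists fixed before the data were examined (pathways of lipid, clock and immune genes, and markers of the cell types of an eyelid), camera was run with a preset correlation between genes of 0.01 and adjusted over the lists within a contrast. It was also run with an estimated correlation. Each list was further given a count of genes passing when adjusted over the list alone, and a score per library, the mean log2(FPKM + 1) of its genes. Scores were compared between diets by a 2-sided exact permutation test of the diet labels within each time, with 216 permutations and a smallest possible p of 0.00926.

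Genes are named by a rule fixed beforehand: among called genes with a mean log2 CPM of at least 1 and a regular gene name, up to 6 with the largest rise and up to 6 with the largest fall, up to 3 with the smallest p of each called list, the clock genes, and where fewer than 5 genes were called, the 5 with the smallest p. The averaged comparison also required the same sign at all 3 times, and a comparison at 1 time required that the libraries of both groups did not overlap. The CPM for this rule came from the recovered reads. Symbols outside the rule are said to have been chosen after their values were seen. Some genes that the rule would name are withheld and not reported here.

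The test was checked on simulated data with 100 genes changed 2-fold and 100 genes changed 4-fold among 13224. It recovered 87% and 100% of them for the averaged diet effect, 58% and 95% for the diet effect at 9h, 57% and 98% for the time effect in control mice, and 31% and 80% for the interaction. False calls made up 2.5% to 6.5% of the calls. The simulated noise was independent for each gene, without shifts shared by the genes of a library, so these rates may not carry over to the real libraries.

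Alternatives fixed beforehand were a pseudocount of 0.1, no filter on low values, a fit of the compared groups alone, the skeletal muscle score as a covariate, the replicate number as a block, unadjusted p under 0.05 with at least 2-fold change, an estimated correlation for the lists, and leaving out each library in turn. Alternatives chosen after seeing the data were a median-of-ratios rescaling, limma-voom on the recovered reads, leaving out both libraries highest in immediate early genes, and the score of those genes as a covariate. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 was used for the rest, and figures were drawn with matplotlib 3.10.9.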

Results

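Gene expression was measured in eyelid tissue of mice on a standard or a high-fat diet at 3 times of day, with 2 libraries per diet and time and 12 in all. The recovered depth was 14096362 to 17889158 reads per library. Scd1, a stearoyl-CoA desaturase abundant in lipid-secreting glands, took the most reads in 10 of the 12 libraries. The first principal component held 29.1% of the variance and the second 22%. The series title names diurnal rhythm and hyperlipidemic mice, so the comparisons are diet, time of day, and whether one depends on the other.

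Genes of the interferon response were lower in high-fat mice at every time. Isg15, a ubiquitin-like protein induced by interferon (ENSMUSG00000035692, GRCm38 chromosome 4, 156199424 to 156200818, minus strand), averaged 94.2 ± 26.5 FPKM in controls and 14.1 ± 7.31 FPKM in high-fat mice (SD, n = 6 each). Its log2 fold change averaged over times was -2.77 ± 0.34 (SE). Gbp2, an interferon-induced guanylate-binding protein (ENSMUSG00000028270, chromosome 3, 142620602 to 142638008, plus strand), was at 130.9 ± 37.2 FPKM in controls and 20.3 ± 13.7 FPKM in high-fat mice, a log2 fold change of -2.81 ± 0.35. The other genes with the largest falls were Gzma, a granzyme of cytotoxic lymphocytes (-2.62 ± 0.43), Igtp, an immunity-related GTPase (-2.56 ± 0.33), Ifit1, which binds viral RNA (-2.50 ± 0.27), and Ubd, a ubiquitin-like modifier (-2.47 ± 0.28). limma adjusted p was 0.0031 to 0.0157 for these 6 genes. All 24 measured genes of the interferon list fell, over all genes tested and adjusted over the list alone, with a median log2 fold change of -1.76. Oas1a, an oligoadenylate synthetase, fell from 16.3 ± 3.73 to 2.48 ± 1.05 FPKM, Bst2 (tetherin) from 55.7 ± 16.8 to 15.6 ± 3.24 FPKM, and Gbp3 from 16.1 ± 4.67 to 3.91 ± 1.06 FPKM, each with a limma adjusted p of 0.00125. Oas1a, Gbp2, Gbp3 and the Ifit genes belong to families with close copies, between which the authors' counting could have split reads. The library scores of the list were lower in the high-fat libraries than in each control library at the same time, with a mean difference of -1.83 (exact permutation p = 0.00926, the smallest possible, and 0.102 adjusted over the 33 lists). The camera adjusted p was 4.61e-44 with the preset correlation and 0.214 with an estimated correlation. The score separation was not particular to this list. T cell scores were lower, and core clock scores higher, in each high-fat library than in each control library at the same time. Both lists thus share the exact permutation p of 0.00926.

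**Figure D1:**
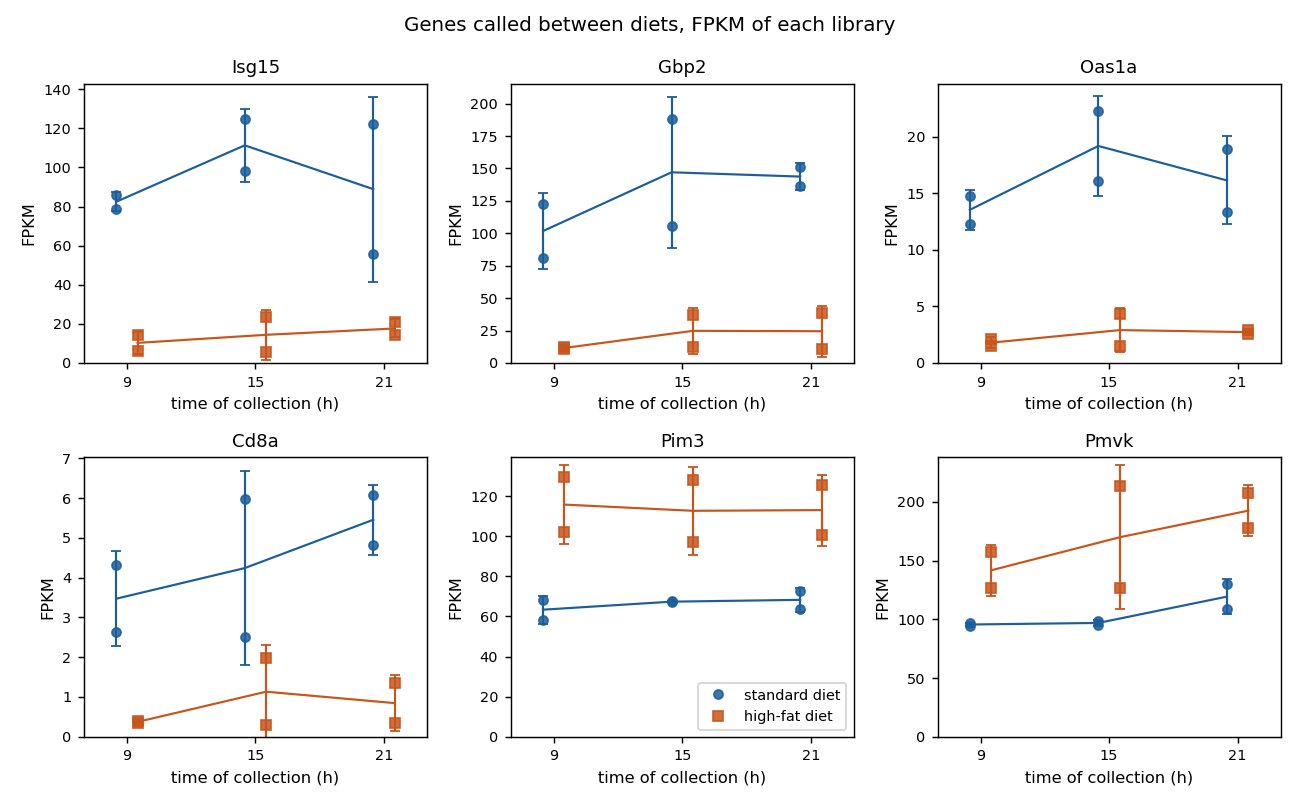
FPKM (vertical axis, linear from 0) of 6 genes called between diets against time of collection in h, with points for libraries, lines through group means and bars for the SD of 2 libraries. Isg15, Gbp2, Oas1a and Cd8a lie lower and Pim3 and Pmvk higher in high-fat mice, for Isg15 at 94.2 FPKM in controls against 14.1 FPKM.

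Markers of lymphocytes were also lower averaged over times. In the T cell list 6 of 13 measured genes fell over all genes tested and 11 adjusted over the list alone. Cd8b1 and Cd8a, the chains of the CD8 coreceptor, had log2 fold changes of -1.79 ± 0.24 and -1.62 ± 0.26. Cd8a (ENSMUSG00000053977, chromosome 6, 71373427 to 71379173, plus strand) was at 4.39 ± 1.56 FPKM in controls and 0.784 ± 0.705 FPKM in high-fat mice. Cd2, an adhesion molecule of T cells, changed by -0.83 ± 0.12. Cd79b, a signalling chain of the B cell receptor, fell by 0.84 on the log2 scale, the 1 called gene among 7 of the B and plasma cell list, and 4 passed adjusted over the list alone. No gene of the 16 in the macrophage list was called (1 adjusted over the list alone, Fcgr1, -0.82 ± 0.19), and 15 had negative values. In the list of inflammatory cytokines 2 of 24 fell, Cxcl10, a chemokine induced by interferon, by 1.75 and Tnf by 0.80, and the same number passed adjusted over the list alone. Camera called all 4 lists, with adjusted p of 7.29e-11 (T cell), 0.00279 (B and plasma cell), 0.000842 (macrophage) and 0.00216 (inflammatory cytokines). The adjusted p with an estimated correlation was 0.355, 0.526, 0.708 and 0.761 in the same order. Without HF_15h replicate 2 the adjusted p of the macrophage list was 0.0843 and that of the cytokine list 0.167, and the latter was 0.0775 without CTL_9h replicate 2 and 0.051 without HF_21h replicate 3. Leaving out 1 library also ended the calls of Gzma, Cd8a and Cd79b, whose adjusted p was 0.0619, 0.0501 and 0.115 without CTL_9h replicate 2, and of Tnf, with 0.11 without CTL_15h replicate 3. At 21h alone the B and plasma cell list was not called (median -0.02, camera adjusted p 0.277). Its score difference at that time turned from -0.19 to 0.30 without CTL_21h replicate 2 and to 0.25 without HF_21h replicate 3.

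Lists of lipid genes had slightly higher medians in high-fat mice, with few genes called. Pmvk, a kinase of cholesterol synthesis, rose by 0.67 ± 0.13 on the log2 scale (n = 6 each). Of the 25 measured genes of this pathway 9 passed adjusted over the list alone, and 24 had positive values. Among 26 genes of meibocytes and sebocytes Soat1, which esterifies cholesterol, rose by 0.42 ± 0.08 and Lpcat4, an acyltransferase of phospholipids, fell by 0.42 (3 higher and 1 lower passed adjusted over the list alone). No gene passed either way among 25 of fatty acid synthesis, where Acacb had a value of 0.38 ± 0.09. None of 15 adipocyte genes was called and 3 passed adjusted over the list alone, with Plin4, a coat protein of lipid droplets, at 0.47 ± 0.12. Median log2 fold changes were 0.24 for cholesterol synthesis, 0.21 for meibocyte genes, 0.17 for adipocyte genes, 0.16 for fatty acid synthesis and 0.14 for fatty acid oxidation. Camera called these 5 lists (adjusted p 1.7e-09, 1.58e-06, 0.000517, 0.000114 and 3.91e-06). The adjusted p with an estimated correlation was 0.435, 0.526, 0.435, 0.435 and 0.526.

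The other named rises were Rasd1, a small GTPase induced by glucocorticoids (1.46 ± 0.737 to 6.2 ± 2.87 FPKM), Ffar4, a receptor of long-chain fatty acids (5.92 ± 1.96 to 11.2 ± 2.98 FPKM), Pim3, a serine/threonine kinase (66.3 ± 4.77 to 113.8 ± 15.4 FPKM), and Aadacl3 (6.77 ± 1.13 to 12.6 ± 3.63 FPKM). Their log2 fold changes were 1.49 ± 0.29, 0.83 ± 0.14, 0.76 ± 0.10 and 0.78 ± 0.16, with limma adjusted p of 0.0322, 0.0176, 0.0049 and 0.0491. Leaving out 1 library ended the calls of Rasd1, Ffar4, Aadacl3, Pmvk, Soat1 and Lpcat4. Without CTL_9h replicate 2, for example, their adjusted p was 0.119, 0.063, 0.169, 0.106, 0.145 and 0.127. For most of these genes other libraries had the same effect. The call of Pim3 was kept in each of these 12 fits.

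Cell cycle genes were lower as a list, with 30 of 30 values below 0 and a median of -0.25. Rrm2, a subunit of ribonucleotide reductase, fell from 10.7 ± 1.24 to 7.85 ± 0.618 FPKM and was the 1 gene called, and 11 passed adjusted over the list alone. Camera gave an adjusted p of 2.16e-10, and 0.355 with an estimated correlation. The immediate early genes had a median of 0.52 with no gene called and 2 passing adjusted over the list alone, Egr3 (0.40 ± 0.09) and Egr2 (0.53 ± 0.13), both transcription factors. Their scores were 5.65 in HF_15h replicate 6 and 5.83 in HF_21h replicate 6, and 4.06 to 4.82 in the other 10 libraries. The mean score difference of 0.66 was 0.41 without the former, 0.38 without the latter and 0.13 without both. The glucocorticoid targets had a median of 0.25, with no gene called and 3 passing adjusted over the list alone, Per1 (1.01 ± 0.24), Klf9 (0.47 ± 0.11) and Errfi1 (0.84 ± 0.24). Camera adjusted p was 1.39e-07 and 7.18e-06 for these 2 lists, and 0.526 and 0.435 with an estimated correlation. The core clock list had a median of 0.16 (camera adjusted p = 0.000774, and 0.355 with an estimated correlation), with no gene called and Per1, Ciart and Nfil3 passing adjusted over the list alone. A further 3 lists were close to the threshold, without a gene passing either way: stressed epidermis (median -0.31, adjusted p 0.0414), hair follicle (0.13, 0.0259) and ribosomal proteins (-0.05, 0.0469). Their adjusted p with an estimated correlation was 0.761, 0.761 and 0.785, and leaving out 1 of several libraries ended each call, with adjusted p up to 0.799, 0.956 and 0.62.

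The remaining lists were not called for diet averaged over times. Their median log2 fold changes were -0.09 for skeletal muscle, -0.18 for keratinocytes, -0.14 for conjunctiva, -0.09 for lacrimal and salivary acini, -0.10 for melanocytes, -0.28 for neutrophils, 0.09 for mast cells and -0.05 for extracellular matrix. They were 0.05 for endothelium, 0.07 for Schwann cells, -0.29 for red blood cells, -0.03 for heat shock proteins and 0.03 for insulin and IGF signalling. They were -0.10 for antioxidant genes, -0.04 for the respiratory chain and 0.10 for mitochondrially encoded genes. In 1 case a gene passed adjusted over the list alone, upward, among the Schwann cell genes.

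**Figure D2:**
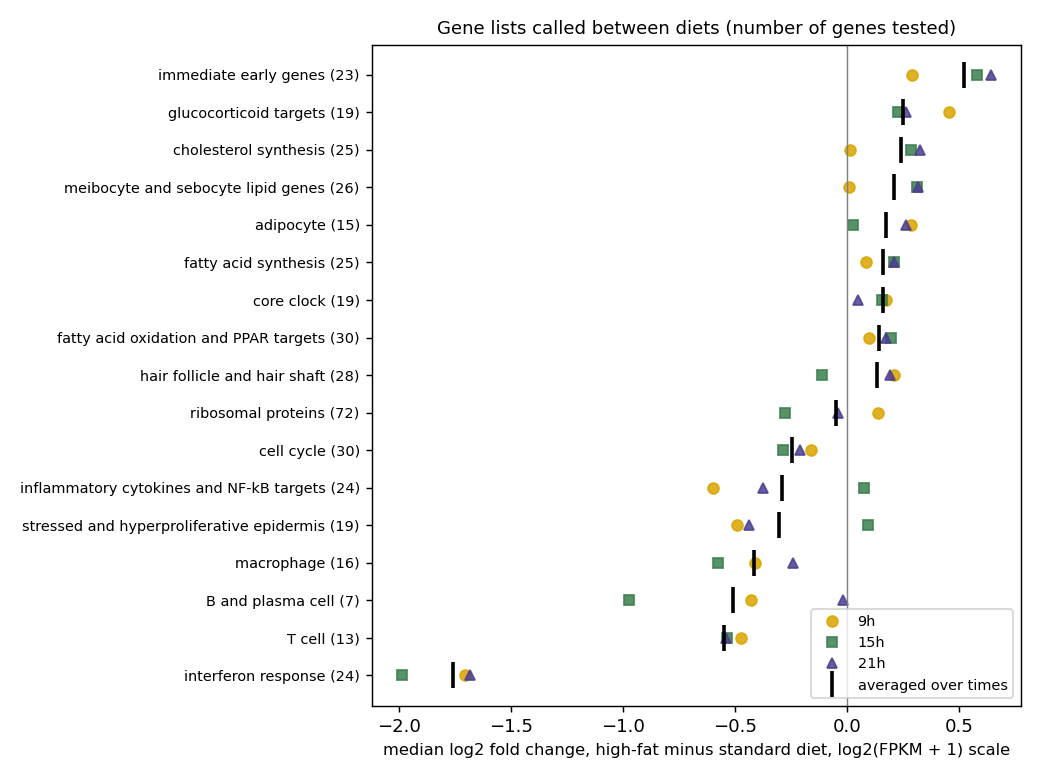
Median log2 fold change, high-fat minus standard diet (horizontal axis, log2(FPKM + 1) scale), of the 17 lists called by camera with the preset correlation, at each time (coloured points) and averaged (black bars), with the number of genes tested in brackets. The interferon list stands lowest, at an average of -1.76, and no list kept its call with an estimated correlation.

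Across all genes, 262 of 13228 were called for diet averaged over times, 27 higher and 235 lower in high-fat mice (limma, 6 libraries against 6). Of these, 103 fell and 1 rose at least 2-fold, and 257 had the same sign at all 3 times, as did 38.7% of all genes tested. The called genes were selected by their average over the same times, which favours an equal sign, so the 257 are no independent evidence. None of the 33 lists held 223 of the 262. The count was 143 without CTL_15h replicate 3, 145 without CTL_9h replicate 2, 159 without HF_21h replicate 3 and 169 without CTL_21h replicate 1. The higher genes among the called moved most, to 2 without CTL_9h replicate 2, 5 without CTL_15h replicate 2, 46 without HF_9h replicate 6 and 62 without HF_9h replicate 7, while the lower ones stayed within 136 to 267.

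At single times, with 2 libraries against 2 and all 12 in the fit, the called genes were again lower in high-fat mice. At 15h 8 genes fell. Oas1a was at 19.2 ± 4.4 FPKM in controls and 2.91 ± 1.95 FPKM in high-fat mice (log2 fold change -2.45 ± 0.32), and Bst2 at 67.8 ± 21.1 and 13.2 ± 2.85 FPKM (-2.26 ± 0.25). The other log2 fold changes were -1.50 for Dhx58, an RNA sensor of the RIG-I family, -1.46 for Cxcr3, the receptor of Cxcl10 on lymphocytes, -1.12 for Parp9 and -1.11 for Rnase6, a ribonuclease of phagocytes. The last 2, Morn2 (-0.89 ± 0.11) and the predicted gene Gm5431 (-1.40 ± 0.17), were chosen after their values were seen. At 21h Cxcr3 (ENSMUSG00000050232, chromosome X, 101731535 to 101734269, minus strand) was the 1 gene called, at 3.04 ± 0.0754 FPKM in controls and 0.647 ± 0.129 FPKM in high-fat mice (limma adjusted p = 0.0429). Next by p at 21h, and not called, were Parp9 (-1.24), Gbp3 (-1.94), Slfn2 (-1.26) and Oas1a (-2.18). At 9h limma called no gene, with 955 at an unadjusted p under 0.05, and limma-voom on recovered reads also called 0, with 1055. The smallest adjusted p at 9h was 0.0807, for Ifit1bl1 (-2.12 ± 0.25), Parp9 (-1.13 ± 0.14) and Ifit3b (-2.41 ± 0.30), followed by Oas1a (-2.38) and Gm5431 (-1.26).

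The interferon list moved alike at the 3 times: 24 of 24 genes passed adjusted over the list alone at each of 9h, 15h and 21h, with medians of -1.71, -1.99 and -1.69. Over all genes 0, 2 and 0 of them were called. Camera adjusted p was 8.04e-43, 8.17e-32 and 4.76e-45, and 0.229, 0.443 and 0.203 with an estimated correlation. In the T cell list 3, 7 and 7 of 13 genes passed adjusted over the list alone. Cholesterol synthesis genes had medians of 0.01, 0.28 and 0.32 and meibocyte genes of 0.01, 0.31 and 0.32 at 9h, 15h and 21h, and no gene of either list passed at a single time. Without HF_9h replicate 6 the score difference at 9h was 0.24 for both lists, and without HF_9h replicate 7 it was -0.09 and -0.19. In all, camera called 16, 17 and 15 lists at the 3 times. Those not called for the average were, at 9h, conjunctiva and neutrophils (lower) and extracellular matrix, endothelium and mitochondrially encoded genes (higher). At 15h they were skeletal muscle, antioxidant genes and the respiratory chain (lower) and keratinocytes (higher, median 0.40), and at 21h keratinocytes (lower, -0.55) and mast cells (higher). Several of these directions rested on 1 library. The score difference at 9h turned from -0.60 to 0.16 for neutrophils without CTL_9h replicate 2, and from 0.22 to -0.06 for extracellular matrix and 0.22 to -0.03 for endothelium without HF_9h replicate 6. For keratinocytes it turned from 0.36 to -0.37 at 15h without HF_15h replicate 2 and went from -1.04 to -0.42 at 21h without CTL_21h replicate 1. Ribosomal proteins were called higher at 9h (median 0.14) and lower at 15h (-0.28). None of the calls at single times held with an estimated correlation. Across genes, the diet effects at 9h and 21h had a Pearson r of 0.56, those at 9h and 15h 0.40 and those at 15h and 21h 0.46, over genes that are not independent replicates.

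The counts at single times moved with the libraries fitted. At 9h 155 genes were called without HF_9h replicate 7, of which 136 were higher and 19 lower in high-fat mice, 25, all lower, without HF_15h replicate 2 or 6, 0 or 1 without any other library, and 55 in a fit of the 4 libraries of that time. Without both libraries high in immediate early genes, HF_15h replicate 6 and HF_21h replicate 6, it was 41. At 15h the count was 72 without HF_15h replicate 2 and 4 without HF_15h replicate 6, and 0 to 2 without any other library. At 21h it was 27 without HF_15h replicate 2 or 6 and 0 without any other library. At 15h limma-voom on recovered reads called 0 genes, with 1442 at an unadjusted p under 0.05.

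The effect of diet was not shown to differ between times for any gene by the F test adjusted over all genes. The F test of the interaction called 0 of 13228 genes, with 405 at an unadjusted p under 0.05 and a smallest adjusted p of 0.999, and limma-voom on recovered reads also called 0, with 375. Without HF_9h replicate 7 it also called 0, with 1806 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0684. The smallest p values were those of Morn2 (0.00027), Aldoa, a glycolytic enzyme abundant in muscle (0.000589), Ear2, an RNase of eosinophils (0.00103), Endou (0.00134) and Myoc (0.00137). Per2 had an unadjusted p of 0.00547 in the F test with all libraries, and no core clock gene passed this F test adjusted over the list alone. In simulated data with independent noise for each gene, the same test recovered 31% of 2-fold and 80% of 4-fold interactions.

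Clock genes changed with the time of day in control mice. Per2, a repressor of the circadian clock (ENSMUSG00000055866, chromosome 1, 91415982 to 91459324, minus strand), rose from 1.47 ± 0.23 FPKM at 9h to 6.31 ± 1.01 at 15h and 14.3 ± 1.32 at 21h (SD, n = 2 each). The log2 change from 9h to 21h was 2.63 ± 0.18 with a limma adjusted p of 0.0046. Npas2, an activator that pairs with Arntl (ENSMUSG00000026077, chromosome 1, 39193731 to 39363236, plus strand), fell from 4.74 ± 0.00492 FPKM at 9h to 1.54 ± 0.14 at 15h (limma adjusted p = 0.0284). The third called gene was Inmt, a methyltransferase, at 7.84 FPKM at 9h and 28.9 FPKM at 21h (1.79 ± 0.18, limma adjusted p = 0.0284). The call of Per2 ended without CTL_9h replicate 2 (adjusted p 0.126), without CTL_21h replicate 1 (0.0674) and with the muscle score as a covariate (0.185), at log2 changes of 2.54, 2.54 and 2.57. Those of Npas2 and Inmt also ended without CTL_9h replicate 2 (0.506 and 0.13) and without several other libraries. Next by p, and not called, were Cdc20 (-1.01) and Aldoa (-1.52). Of the 19 measured clock genes 2 were called over all genes and 11 passed adjusted over the list alone. These 11 included Per3 (largest difference 1.85), Dbp (1.83), Nr1d2 (1.42), Tef (1.27) and Ciart (1.04), which were higher at 15h or 21h than at 9h. Arntl was lower at 21h than at 9h (-0.93), Nr1d1 lower at 21h than at 15h (-1.35), and Cry1 higher at 21h than at 15h (0.90). Not passing were Hlf, Per1, Cry2, Nfil3, Clock, Bhlhe40, Bhlhe41 and Rora, with largest differences from -0.56 to 0.64.

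In high-fat mice no gene was called for time of day, with 1155 at an unadjusted p under 0.05 (limma, smallest adjusted p 0.221), and limma-voom on recovered reads also called 0, with 1128. The smallest p values were those of Myod1, a muscle transcription factor (-1.14 from 9h to 21h), and Per2, followed by Ppp1r27 (-1.75), Eepd1 (-0.74) and Ear2 (-1.26). Per2 was at 3.46 ± 0.691, 6.78 ± 1.43 and 12.1 ± 1.64 FPKM at 9h, 15h and 21h, a log2 change of 1.56 ± 0.18 from 9h to 21h. Adjusted over the list alone 4 of 19 clock genes passed, Per2, Per3 (1.2), Cry1 (0.75) and Npas2 (-0.64). That 11 passed in controls and 4 in high-fat mice does not show a difference between diets, since no clock gene passed the F test of the interaction. The diet effect at 21h minus that at 9h was compared after the data were seen. In that comparison 1 of 19 clock genes passed adjusted over the list alone, downward.

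**Figure D3:**
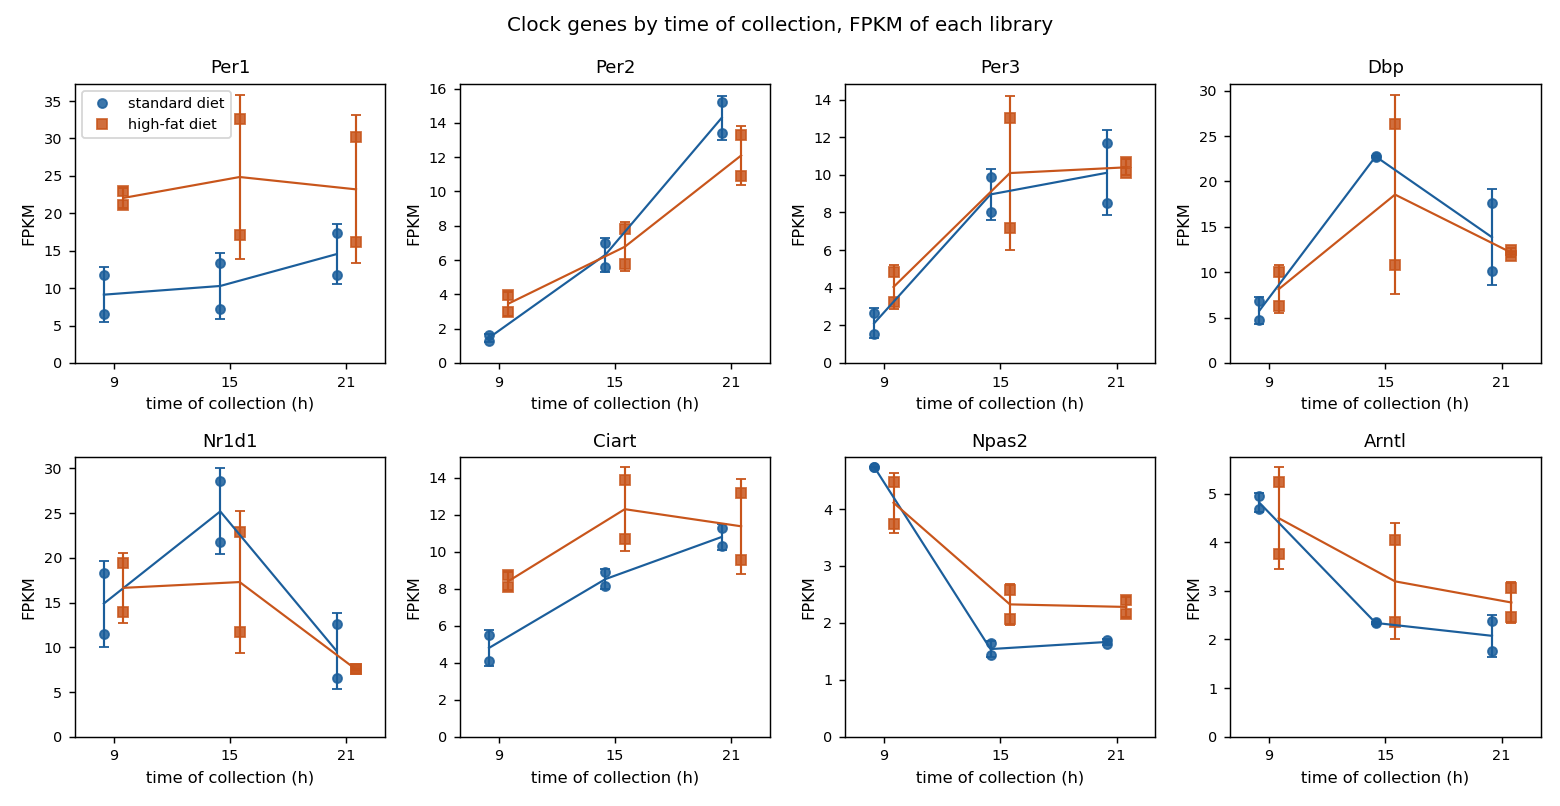
FPKM (vertical axis, linear from 0) of 8 clock genes against time of collection in h, with points for libraries, lines through group means and bars for the SD of 2 libraries. Per2 rises in both diets, from 1.47 to 14.3 FPKM in controls and from 3.46 to 12.1 FPKM in high-fat mice, and Per1 is higher in high-fat mice at each time.

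At 9h Per2 and Ciart were higher in high-fat mice when adjusted over the list alone, by 0.85 ± 0.18 and 0.71 ± 0.18, and neither passed over all genes. Without CTL_9h replicate 2 neither passed (0.75 ± 0.22 and 0.53 ± 0.21, adjusted over the list alone to 0.185 and 0.297). Nr1d2 (0.75), Per3 (0.70), Tef (0.57) and Per1 (1.24 ± 0.41) had positive values there and did not pass. Per1 was at 9.11 ± 3.61 FPKM in controls and 22.1 ± 1.33 FPKM in high-fat mice at 9h.

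Muscle genes also differed between times, in both diets. The skeletal muscle list had median changes of -0.54 from 9h to 15h and -0.75 from 9h to 21h in controls. In high-fat mice the same changes of this list were -1.02 and -0.775. By the F test 13 of its 26 genes in controls and 23 in high-fat mice passed adjusted over the list alone, and none over all genes. Its library scores were 7.07 to 7.39 at 9h and 6.12 to 6.81 at the later times. Of 72 ribosomal protein genes 34 passed adjusted over the list alone in controls, with a median change of 0.52 from 9h to 21h. In high-fat mice all 72 were also higher at 21h than at 9h, with a median of 0.33 and 0 passing adjusted over the list alone. From 15h to 21h 37 of them passed in this way in high-fat mice, with a median of 0.38. The camera adjusted p was 6.31e-12 for muscle from 9h to 21h in controls and 3.63e-28 for muscle from 9h to 15h in high-fat mice. For ribosomal proteins from 9h to 21h it was 5.21e-20 in controls and 3.76e-18 in high-fat mice. With an estimated correlation these values were 0.857, 0.781, 0.857 and 0.987. The counts for time moved with the libraries fitted. In control mice 3 genes were called with all 12 libraries, 838 without HF_9h replicate 6, 839 without HF_9h replicate 7, and 751 in the 6 control libraries alone, 540 of them higher and 211 lower at 21h than at 9h. It was 8 without HF_15h replicate 2 or 6 and 0 to 2 without any control library or library of HF_21h. In high-fat mice the count was 63 without HF_9h replicate 6 and 3 without HF_15h replicate 2. With the muscle score as a covariate 1 gene was called in controls, and it was none of the 3.

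**Figure D4:**
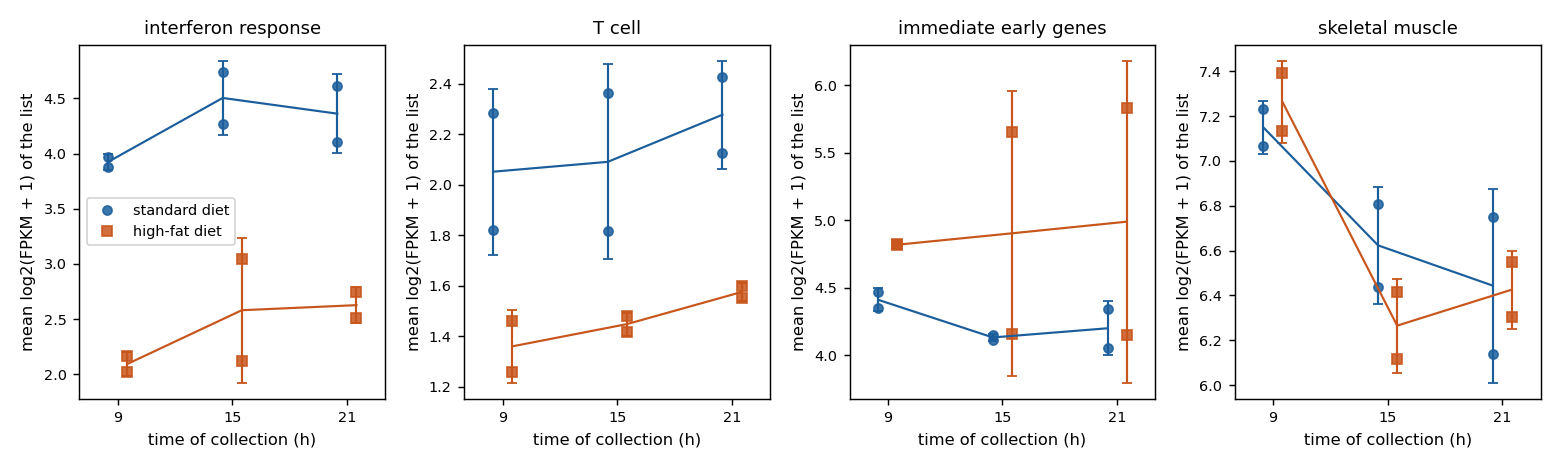
Mean log2(FPKM + 1) of 4 gene lists (vertical axis, not from 0) against time of collection in h, with points for libraries, lines through group means and bars for the SD of 2 libraries. Interferon and T cell scores are lower in each high-fat library than in each control library, 2 high-fat libraries stand apart in immediate early genes at 5.65 and 5.83, and muscle scores are higher at 9h.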

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

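The tests of list differences between times, the score differences without 1 library and both tests of the immediate early genes below were chosen after their results were seen. In the 6 libraries of a diet, a list score or a named gene was looked at for a single library far from the other 5. This was so in 7 of 190 cases, and chance alone gives about 1 in 20. In high-fat mice HF_9h replicate 6 was low in the fatty acid synthesis score (5.07, the others 5.22 to 5.28), low in Gpam, a glycerol acyltransferase (5.21 on the log2(FPKM + 1) scale, the others 5.58 to 5.72), and high in the Schwann cell score (3.77, the others 3.36 to 3.48). HF_9h replicate 7 was high in the score of fatty acid oxidation and PPAR targets (5.12, the others 4.71 to 4.83). HF_15h replicate 2 was low in the red blood cell score (1.93, the others 2.87 to 3.27) and in the glucocorticoid target score (4.5, the others 5.0 to 5.17). Among controls, CTL_21h replicate 1 was low in the hair keratin Krt33b (4.14, the others 5.41 to 6.07).

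For 17 lists, camera with the preset correlation found a diet effect that differed between 2 times, given here as the median difference of log2 fold changes and after correction for the lists and the 3 pairs of times. None was called with an estimated correlation (adjusted p 0.668 to 0.871). Between 9h and 15h the diet effect changed by -0.41 for ribosomal proteins, 0.65 for inflammatory cytokines, -0.45 for skeletal muscle, 0.75 for neutrophils, -0.45 for extracellular matrix and -0.36 for mitochondrially encoded genes. Between 9h and 21h it changed by 0.19 for cholesterol synthesis, 0.32 for meibocyte genes, 0.33 for conjunctiva, 0.11 for fatty acid oxidation and PPAR targets, -0.31 for endothelium, 0.11 for heat shock proteins and 0.30 for immediate early genes. Between 15h and 21h it changed by -0.87 for keratinocytes, 0.23 for the respiratory chain, -0.19 for stressed epidermis and 0.36 for melanocytes. Each list is given only for its pair of times with the smallest p, and several lists also passed for another pair. Between 9h and 15h, for example, the diet effect changed by 0.505 for keratinocytes and 0.512 for stressed epidermis. For 13 of the 17 the score difference between diets turned at 1 or both of the times compared when 1 library was left out. Examples are neutrophils at 9h without CTL_9h replicate 2, extracellular matrix at 9h without HF_9h replicate 6 and keratinocytes at 15h without HF_15h replicate 2. Differences that rounded to 0.0 with all libraries were not counted as turning. Of these, cytokines at 15h went to 0.48 without HF_15h replicate 2 and -0.47 without HF_15h replicate 6. Conjunctiva at 21h went to 0.36 without HF_21h replicate 3 and -0.36 without HF_21h replicate 6. The respiratory chain at 21h went to 0.08 without CTL_21h replicate 1 and -0.08 without CTL_21h replicate 2. The difference for cytokines at 9h went from -0.64 to -0.02 without CTL_9h replicate 2, and that for keratinocytes at 21h from -1.04 to -0.42 without CTL_21h replicate 1.

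Immediate early genes were high in HF_15h replicate 6 and HF_21h replicate 6, with a gap of 0.83 between the lower of these 2 scores and the next library. An effect of the diet in every high-fat mouse cannot be told apart: 1 of the 6 high-fat libraries, HF_21h replicate 3, lay within the range of the 2 controls of its own time, HF_15h replicate 2 lay above its controls by only 0.007, and the test was changed after a first form that pooled the controls over times. Handling at tissue collection may account for the rise, since such genes respond within minutes, and no record of collection was used here, so that it cannot be told apart from a response of these mice to the diet. Without both libraries 224 genes were called for diet averaged over times, 162 of them among the 262.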

How the results depend on the processing

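Settings chosen after seeing the data were the median-of-ratios rescaling, limma-voom on recovered reads, leaving out both libraries high in immediate early genes, and their score as a covariate. The planned DESeq2 test and its size factors were not run, because the table holds FPKM values and not counts. Counts below are in the order diet averaged, 9h, 15h, 21h, interaction, time in controls and time in high-fat mice, against 262, 0, 8, 1, 0, 3 and 0. An unadjusted p under 0.05 with at least 2-fold change gave 113, 122, 154, 136, 74, 193 and 117 genes. A pseudocount of 0.1 gave 249, 0, 2, 0, 0, 3 and 0, and no filter 211, 0, 1, 0, 0, 1 and 0. The muscle covariate gave 177, 0, 0, 0, 0, 1 and 0, the rescaling 245, 0, 9, 2, 0, 4 and 0, and limma-voom 233, 0, 0, 1, 0, 4 and 0. Without both libraries high in immediate early genes the counts were 224, 41, 0, 4, 0, 1 and 0, and with their score as a covariate 236, 24, 0, 2, 0, 1 and 0. A fit of the compared groups alone gave 55 genes at 9h, 0 at 15h, 0 at 21h, 751 in controls and 0 in high-fat mice. Of the clock genes called over time in controls, 2 with all libraries, there were 10 in the fit of controls alone, 1 with no filter, 0 with the muscle covariate, and 1 without both libraries or with their score as a covariate. Under each of these settings that covers it, most calls for diet averaged were lower, but the genes changed: of the 262, 162 were shared without both libraries, 155 with their score as a covariate, 174 with the muscle covariate and 189 with no filter. Of the 17 lists called, an estimated correlation left 0. The cause of these changes was not tested, except that no filter adjusts over 18451 genes and the 2-fold setting drops the adjustment. Fitting the compared groups alone leaves their means and fold changes as they were, so its counts differ only through the estimate of spread and its degrees of freedom.

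Leaving out each library in turn gave 143 to 293 genes for diet averaged, 0 to 155 at 9h, 0 to 72 at 15h, 0 to 27 at 21h, 0 to 0 for the interaction, 0 to 839 for time in controls and 0 to 63 in high-fat mice. Clock genes ranged from 0 to 9 and lists from 14 to 21. A group left with 1 library is assumed there to vary like the others. The 24 interferon genes were called in each of these 12 fits and under each other setting that keeps the adjusted threshold, except 23 in both settings on immediate early genes and 0 with the replicate block, where their median was -1.68 against -1.76.

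The replicate numbers were not taken to pair the libraries: the deviations of same-numbered libraries from their group means had correlations over 0.1 in 3 of 12 pairs (-0.502 to 0.289), and of -0.083 between the controls at 9h and 15h, the only groups to share both numbers. With the replicate block 2 residual degrees of freedom were left, and 0, 1, 0, 0, 0, 0 and 0 genes, 0 clock genes and 18 lists were called. In the 4 control libraries at 9h and 15h alone, 779 genes were called without and 0 with the block.

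Directions turned in these cases, in none of which the gene was called with all libraries. With the muscle covariate, time effects became -0.002 for Bhlhe40 in controls and -0.02 for Hlf, -0.148 for Per1 and -0.116 for Clock in high-fat mice. With the replicate block, Btg2 was at -0.126 for diet averaged, Thbs1 at -0.955 at 9h, Il1f6 at 0.573, Lce1c at 0.774, Lce1f at 0.904 and Mcpt4 at -0.123 at 21h, and Nfil3 at 0.283 for time in high-fat mice. The immediate early list turned down (adjusted p = 1.65e-07) and the ribosomal list up (0.722) with that block, and both libraries high in immediate early genes carry the number 6. With each library left out in turn, Csf3r at 9h ranged from -1.589 to 0.125, turning without CTL_9h replicate 2. For time in high-fat mice Nfil3 ranged from -0.746 to 0.467, turning without HF_15h replicate 2, and Per1 from -0.345 to 0.543, turning without HF_15h replicate 6, as without both libraries high in immediate early genes. Depth limits genes near 1 FPKM.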

Other observations

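The gene groups and tests of the next paragraphs were chosen after the results were seen, except those on substrains and on a single unusual library, which were written before. Beyond the fixed lists, the genes called lower in high-fat mice included those that present antigen. Of 22 measured genes of MHC class I presentation 18 fell, with a median log2 fold change of -0.90, and 8 of 10 of MHC class II presentation fell, with a median of -0.87. All 16 guanylate-binding proteins and immunity-related GTPases fell, with a median of -1.96, and 11 of 13 genes of cytotoxic lymphocytes, with a median of -1.19. These groups were chosen among the called genes, so that their counts are no independent evidence. Many of these genes have close copies, between which reads could be split.

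The fall of interferon genes was set against explanations other than diet. Of 100 splits of the libraries within time only the real one gave as many as 262 calls, and the highest other gave 1. This argues against chance as their source but does not exclude it, since 1 in 100 is the smallest share possible here. The other splits also mix the diets within groups, which widens the spread and lowers their counts. A difference between the sets of mice other than diet was not tested by it. A single unusual library is argued against, since the median of the interferon list stayed within -1.89 to -1.65 whichever was left out. The interferon genes fell by 2.14 and the 13 T cell genes by 1.0 (log2(FPKM + 0.1), difference -1.14, exact permutation p = 0.00926, the smallest possible). A first form without Cd8a and Cd8b1 came out the same way, but leaving out these genes favoured that outcome. The comparison was chosen after the results were seen. It covers only the T cell list as a whole, while Cd8a and Cd8b1 fell further than the interferon genes. It therefore does not argue against CD8 T cells as the sole carriers of the lost interferon transcripts. The comparison also cannot decide whether fewer T cells lowered these genes in other cells, where the fall need not match that of the T cell genes. Mice of different substrains cannot be told apart from diet here, because Nnt, which is deleted in a common substrain, was at most at 0.0326 FPKM in any library under 2 gene models. Diet, a loss of CD8 cells, whose markers Cd8a and Cd8b1 fell by 2.60 and 2.73 on the same scale, and an infection or housing difference between the groups may each be the source and stay open.

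At 9h Per2 and Ciart were higher in high-fat mice when adjusted over the clock list alone, and no clock gene was called over all genes. One unusual control library cannot be told apart as the source: without CTL_9h replicate 2 the 8 genes taken as rising by day besides Per1 kept a median difference of 0.43, but no gene passed, and 2 of 19 had an unadjusted p under 0.05 where 6 had it with all libraries. Induction of Per1 alone cannot be told apart either, since the 2 other genes that passed with all libraries were 0 without that library. A clock running ahead in high-fat mice, at 9h already at a later hour of its cycle, may be the source. The 5 genes taken as falling by day, which it needs lower, differed by a mean of -0.04 with a standard error of 0.07, which decides nothing. The values were -0.29 for Cry1, -0.17 for Npas2, -0.09 for Arntl and for Clock, and 0.43 for Nfil3, which offset the others. Nfil3 and Clock did not pass for time of day in controls. Both groups were chosen after the data were seen, and the rules of these 3 tests were changed after first outcomes had been seen. Under the first rules a clock running ahead had counted as met and the other 2 as argued against.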
